A study of Homo sapiens with 4 samples.

How the data were processed

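Chromatin accessibility was measured by ATAC-seq (transposase insertion into open DNA followed by sequencing) in MCF10A, an established non-tumorigenic human mammary epithelial cell line. The labels name 2 groups of 2 libraries, lettered A and B. One group carried a short hairpin against SNHG8d (shG8d), a form of the small nucleolar RNA host gene SNHG8, and the other a control hairpin (shNC). No label says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

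Per the submitters' processing notes, base calls came from CASAVA 1.4 and the genome build was hg19. The aligner, peak caller, counter and differential test are not given in the sources used here. The authors' deposited table holds 58127 regions. Per the file headers, each region has a log10 normalized value for each of the 4 samples, a log2 fold change, a p-value, an annotation, a distance to the nearest transcription start site (TSS) and a gene symbol. The row identifiers place 33913 regions in a common set, 2755 in a set specific to shG8d and 21459 in a set specific to shNC. The deposited log2 fold change lay within 0.00920 of the log2 ratio of the mean normalized values of the columns labelled shG8d and shNC. The deposited p-value is unadjusted. Starts and ends of regions were not used here, so coordinates are given as chromosome and distance to a TSS, and no GC or motif test was run. Symbols are those of the table. A spreadsheet had turned 96 symbols into dates, and 82 of them were restored through the accession of the nearest promoter with a RefSeq gene table (GRCh38.p14, used for names only).

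Raising 10 to each deposited log10 value gave whole multiples of 1 step per column and region set, for 100% of values within 0.05 reads. The step is what 1 read is worth after the authors' scaling, and dividing by it recovered reads per region. Each of the 4 step sizes recurred in all 3 sets, to a relative difference of at most 6.86e-10, but under different group labels. In the common regions the columns labelled shG8d had the lower steps, and in both specific sets the columns labelled shNC had them. The same physical library therefore carries different labels in different parts of the table. Libraries are named here by the step. The deeper pair (0.842 and 0.807 normalized counts per read) is labelled shG8d in the common regions and shNC in the specific regions. The shallower pair (1.21 and 1.17) carries the opposite labels. In the specific sets the labels go with the set names, but both may come from the same source, so which part of the table has the right labels was left open and no direction is assigned to the knockdown. Within a region the exchange alters only the sign of a difference. The letters A and B were not affected.

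The deeper libraries held 8124488 and 8111839 reads in regions and the shallower libraries 4457248 and 4344212. The median region held 65 and 68 reads in the deeper pair and 48 and 49 in the shallower pair. A count of 3 reads, the limit that a count of 0 allows, corresponds to between 2.42 and 3.62 normalized counts per library, which covers counting error only. Between the libraries of a pair, reads per region differed by more than sampling noise, with a chi-square per region of 2.09 in the deeper and 2.69 in the shallower pair over regions with a mean under 1000 reads, so all 4 were kept as separate libraries.

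The design fixed beforehand assumed either read counts or normalized values. The deposited unit is a log10 value, so the test fixed for normalized values was used. This was limma's moderated test (limma 3.58.1, R 4.3.3) with a mean-variance trend on log2(normalized count + 1), deeper minus shallower pair, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount of 1 understates the change of low regions. Regions needed 10 normalized counts in at least 2 libraries, and the filter removed 0 regions. Reads were simulated from the real means for 58127 regions. The test recovered 48% of 100 regions changed 2-fold and 99% of 100 regions changed 4-fold, and 3.29% of its 152 calls were false. With so few changed regions the adjusted threshold was stricter than in the data, where 13697 regions were called. The recovery in the data may therefore be higher. How the authors chose the regions specific to a group is not given. They may have been chosen from the same libraries, by a difference or otherwise, so p-values within those sets cannot be taken as independent of that choice.

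Annotation classes were compared by Fisher's exact test with all other regions as background, over 8 classes and both directions. Regions are not independent replicates. Gene lists, 19 in number and fixed before the data were examined, were tested over 1 promoter region per gene (11488 genes). This was the region of highest mean signal among those annotated as promoter or within 1 kb of a TSS. The test was camera in limma with a preset correlation of 0.01, with an estimated correlation beside it, for the lists with at least 5 promoter regions. Counts adjusted over the list alone are given beside those over all regions where they differ. The regions named were fixed by a rule beforehand. It takes the 10 largest differences in each direction past the threshold with no overlap between the pairs and 1 region per gene, up to 4 members per list, and SNHG8 and the H1 genes whatever their values. By chance 33.3% of regions show no overlap in 2 against 2. One of the 20, near a sex-chromosome pseudogene, is not reported. The rule returned mainly regions outside promoters, some of high and others of low signal, and 2 further sets were added after that was seen. The first holds promoter regions of any set, and since nearly all of those came from the specific sets, the second holds promoter regions of the common set. Both are limited to a mean under 1000 normalized counts over the 4 libraries. Alternatives were other scalings, another pseudocount, a replicate block, each library left out, other thresholds, voom on the recovered reads, the deposited p-values after adjustment, and thinning. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.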

Results

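ATAC-seq profiles were compared between MCF10A mammary epithelial cells with an SNHG8d hairpin (shG8d, 2 libraries) and with a control hairpin (shNC, 2 libraries). The study's title concerns SNHG8d, histone H1, chromatin condensation and epithelial differentiation, so the question was which regions lost or gained accessibility and whether they lie at epithelial or histone genes. The 58127 regions comprised 9614 promoters, 23117 introns, 21684 intergenic regions and smaller classes. Promoters made up 19.3% of common regions, 13.1% of shNC-specific regions and 9.62% of shG8d-specific regions.

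The group labels contradict each other between parts of the table. In the 33913 common regions the columns labelled shG8d are the deeper libraries, with 0.842 and 0.807 normalized counts per read, and the columns labelled shNC have 1.21 and 1.17. In the 2755 shG8d-specific and 21459 shNC-specific regions the same values appear under the opposite labels. In the specific regions the column labels go with the set names, as medians in shG8d-specific regions were 47.1 and 50.4 under shG8d and 20.2 and 21.8 under shNC. Nothing in the table shows that set names and columns are independent, so this does not settle which part is right. Differences are therefore given between the deeper and the shallower pair. The set of a region gives the label of the deeper pair, which is shG8d in common regions and shNC in both specific sets, and no direction is assigned to the knockdown.

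**Figure D1:**
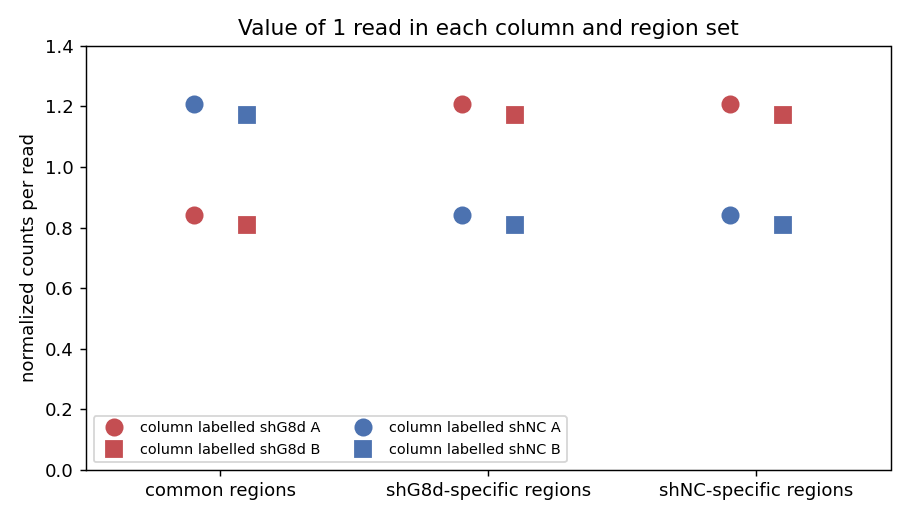
Normalized counts that 1 read is worth (y axis) in each of the 4 columns, by region set (x axis), with circles for letter A, squares for letter B and colours for the group label. The values of the shG8d and shNC columns trade places between the common regions and both specific sets, at 0.842 and 0.807 against 1.21 and 1.17.

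Accessibility differed between the pairs at 13697 of 58127 regions (limma, adjusted p under 0.05), and 6810 of them differed at least 2-fold. In the common regions 3634 were higher and 5082 lower in the deeper pair, labelled shG8d there. In the shNC-specific regions 2842 were higher and 210 lower in the deeper pair, labelled shNC there. In the shG8d-specific regions 1928 were lower and 1 was higher in the deeper pair, again labelled shNC there. The exception was a promoter region of CAST, the calpain inhibitor calpastatin. The number of calls changed with the library left out, to 4629 and 6202 without the deeper pair's A and B and to 19153 and 13748 without the shallower pair's A and B. In each of these fits the spread came from the complete pair alone, so a left-out library also alters which pair supplies it. Calls in common regions were then 1301 higher and 1632 lower, 1529 and 2425, 5177 and 6718, and 3958 and 4695, in the same order. In shNC-specific regions they were 744 and 46, 946 and 68, 4562 and 673, and 3009 and 334. In shG8d-specific regions 905, 1233, 2020 and 1750 were lower. By label alone, then, the libraries called shG8d had the more numerous losses in the common and shNC-specific regions, and nearly all gains in the shG8d-specific regions. The label names different libraries in the common and in the specific regions. With equal library totals alone, 1220 shNC-specific regions were higher and 1357 lower in the deeper pair, so the majority there rests on the scaling.

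The sets differed in how far they moved. The median log2 difference, deeper minus shallower, was −1.20 over shG8d-specific regions, 70.0% of which passed the test. It was 0.24 over shNC-specific regions, of which 14.2% passed, and −0.12 over common regions, of which 25.7% passed. Median normalized counts per library in the shNC-specific regions were 38.7 and 37.9 in the deeper pair and 33.8 and 32.8 in the shallower pair. In the shG8d-specific regions they were 20.2 and 21.8 against 47.1 and 50.4. With equal library totals as the only scaling, the median of all regions moved by −0.35, and the share of calls higher in the deeper pair went from 41.7% to 9.87% in common regions and from 93.1% to 47.3% in shNC-specific regions.

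Promoters stood higher in the deeper pair than other regions did. Of the promoters, 22.2% were called higher in the deeper pair, against 8.95% of all other regions (odds ratio 2.90, Fisher's exact test, adjusted p = 4.18e-263), and 10.1% were called lower against 12.9% (odds ratio 0.762). Regions in 5′ UTRs and coding exons were also called higher more often (odds ratios 1.48 and 1.44), though in common regions the odds ratios were 1.34 (adjusted p = 0.0278) and 1.17 (adjusted p = 0.414), while intergenic regions and introns were called higher less often (odds ratios 0.626 and 0.655). The excess was present in common regions, where 19.9% of promoters were called higher (odds ratio 2.66) and the deeper pair is labelled shG8d. It was also present in shNC-specific regions, where 29.7% of promoters were called higher (odds ratio 3.51) and the deeper pair is labelled shNC. In common regions the median log2 difference was 0.06 at promoters, −0.18 at intergenic regions and −0.17 in introns. Per library, the promoter median in common regions lay above the intergenic median by 0.65 and 0.71 on the log2 scale in the deeper pair and by 0.52 and 0.35 in the shallower pair.

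**Figure D2:**
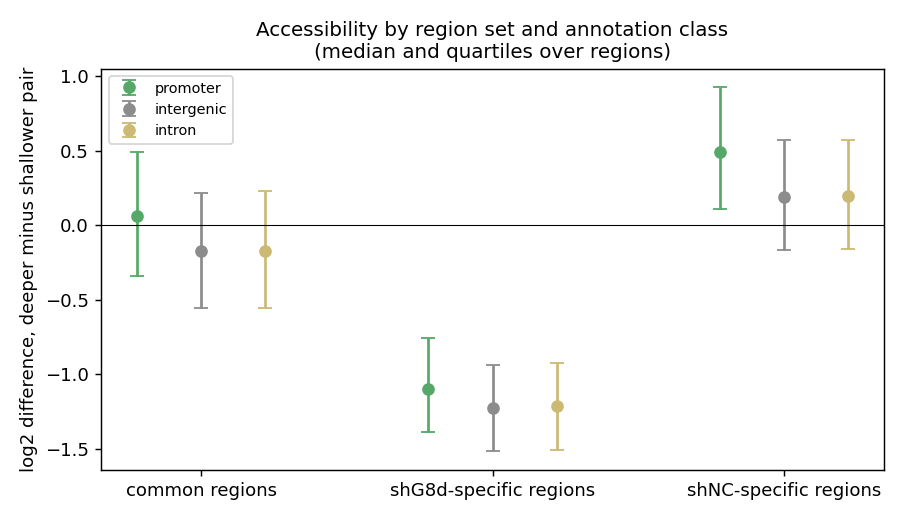
Log2 difference in accessibility, deeper minus shallower pair (y axis), for promoters, intergenic regions and introns of each region set (x axis). Points are medians over regions and bars span the quartiles. Promoters lie above the other classes in each set, with medians of 0.06, −1.10 and 0.49.

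Core histone genes were the only list called by camera with its preset correlation. Of 28 core histone genes with a promoter region, 8 were lower in the deeper pair and 0 higher over all regions tested, and 9 were lower when adjusted over the list alone, with a median log2 difference of −0.42 against 0.14 over all 11488 promoter regions. The adjusted p of camera was 0.000191 with the preset correlation and 0.912 with an estimated correlation. The 0.912 was shared by every list tested, and the unadjusted p of camera for core histones was 0.117 there. Over the 22 promoter regions of the common set alone the adjusted p of camera was 0.00691. Over sums of all regions annotated to a gene, for 32 genes, it was 0.00962. With each library left out in turn the median log2 difference of the list lay between −0.53 and −0.34. With equal library totals alone, 19 of the 28 were called lower and the median was −0.77. The largest difference was at HIST1H2BC, an H2B gene, in a region annotated to the gene's end 825 bp from its TSS, at 30.5 ± 3.2 normalized counts in the deeper and 72.4 ± 16.9 in the shallower pair (SD, n = 2 each; log2 difference −1.20, SE 0.296, limma adjusted p = 0.00736). HIST1H4B, an H4 gene, had a log2 difference of −1.07 (SE 0.240, limma adjusted p = 0.00419), and HIST1H2BF and HIST1H3A, of H2B and H3, had −0.87 and −0.82 (adjusted p = 0.00931 and 0.0170). Among the genes in the histone clusters, 24 of 25 estimates were below 0. All 3 genes outside the clusters, H2AFX, H3F3A and H3F3B, had estimates above 0, a split seen after the values. Genes of a cluster lie close together, so their estimates are not independent. Whether other regions around the clusters moved likewise was not tested. Without the deeper pair's replicate A, only the promoter of HIST1H2BC remained called, and the adjusted p of HIST1H4B, HIST1H2BF and HIST1H3A was 0.0605, 0.207 and 0.170. Without its replicate B, 4 were called lower and HIST1H3A had an adjusted p of 0.0601. Of the called members, 7 lie in common regions, where the deeper pair is labelled shG8d, but HIST1H2BC lies in the shG8d-specific set, where it is labelled shNC.

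**Figure D3:**
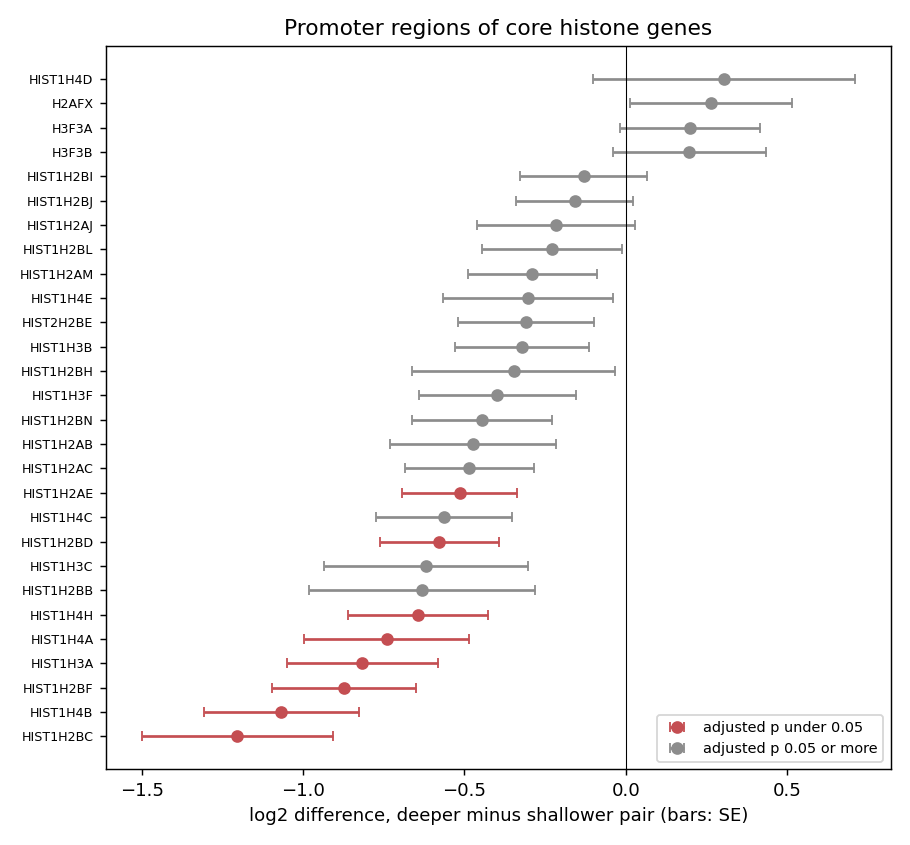
Log2 difference, deeper minus shallower pair (x axis), at the promoter region of each of 28 core histone genes (y axis), with standard errors as bars. The 8 in red have an adjusted p under 0.05 and all lie below 0, between −1.20 and −0.51.

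Linker histone H1, the protein named in the title, showed no shared direction. Which H1 gene was called depended on the library left out. With all 4 libraries HIST1H1D was the 1 of 5 H1 genes with a promoter region to pass, in a common region at 28.1 ± 5.5 normalized counts in the deeper and 59.6 ± 6.3 in the shallower pair on chromosome 6 (log2 difference −1.07, SE 0.309, limma adjusted p = 0.0182). This call was lost without the deeper pair's replicate B, where the log2 difference of HIST1H1D was −0.87 (adjusted p = 0.148). The promoter estimates were 0.03 for HIST1H1C, 0.42 for HIST1H1E, −0.67 for HIST1H1B (shG8d-specific, the others shNC-specific) and −0.0019 for H1FX, with adjusted p of 0.941, 0.277, 0.0967 and 0.997. HIST1H1B passed without the deeper pair's replicate B (−1.11, adjusted p = 0.0347) and without the shallower pair's replicate A (−0.87, adjusted p = 0.0108). Scaled to equal library totals alone, 2 of the 5 were called lower. A common region at the end of HIST1H1C, 1183 bp from its TSS, was lower in the deeper pair (log2 difference −0.66, SE 0.202, adjusted p = 0.0243). That call was lost without either deeper library (adjusted p of 0.143 and 0.176). A shG8d-specific region 25695 bp from the TSS of HIST1H1A was lower too (−1.45, SE 0.368, adjusted p = 0.00875), with an adjusted p of 0.0727 without the deeper pair's replicate A. A common region, 25004 bp from the TSS of HIST1H1A, was at 0.08 (adjusted p = 0.843). No region of H1F0 passed, nor the intronic region of H1FOO.

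The region at the SNHG8 promoter on chromosome 4, 103 bp upstream of the TSS, had 103.9 ± 7.7 normalized counts in the deeper pair, labelled shG8d there, and 81.7 ± 17.8 in the shallower pair. The log2 difference of 0.36 (SE 0.228) did not pass the test (limma adjusted p = 0.267), although it did without the shallower pair's replicate A (0.58 for SNHG8, adjusted p = 0.0470). A hairpin acts on the RNA, which ATAC-seq does not measure, so this value checks neither the knockdown nor the labels.

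Epithelial genes went both ways, as promoters did in general. Of all 11488 promoter regions, 2327 (20.3%) were called higher in the deeper pair and 1227 (10.7%) lower. These shares are the background for the main counts of this list and the next ones. Of 27 epithelial junction and identity genes with a promoter region, 9 were higher and 4 lower in the deeper pair (camera adjusted p = 0.867), and 10 were higher when adjusted over the list alone. EPCAM, an epithelial adhesion molecule, and CDH1, which encodes E-cadherin, were higher, both in shNC-specific regions, with log2 differences of 1.32 (SE 0.308, adjusted p = 0.00526) and 1.07 (SE 0.247, adjusted p = 0.00490). TJP1, the tight-junction protein ZO-1, was lower in a common region (−1.19, SE 0.218, adjusted p = 0.00103), as was the epithelial transcription factor gene GRHL2 (−0.84, SE 0.184, adjusted p = 0.00354). The EPCAM call was lost without the deeper pair's replicate A (adjusted p = 0.0547) and the CDH1 call without its replicate B (adjusted p = 0.0767). Counts for the whole list were then 2 higher with 1 lower, and 2 higher with 2 lower. Without the shallower pair's replicate B they were 5 higher and 5 lower. With equal library totals alone they were 2 higher and 7 lower.

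The squamous differentiation list had 2 of 16 promoters higher and 2 lower in the deeper pair (median log2 difference −0.01). EVPL, the cornified envelope gene envoplakin, was higher in a common region (1.22, SE 0.284, adjusted p = 0.00522), and the desmocollin gene DSC2 was lower in a shG8d-specific region (−1.07, SE 0.279, adjusted p = 0.00994), though not without the deeper pair's replicate B (−0.87, adjusted p = 0.106). Of 10 luminal genes 3 were higher (4 when adjusted over the list alone), led by ALDH1A3 in a shNC-specific region (1.51, SE 0.315, adjusted p = 0.00266), and 2 were lower. The region of CD24, 1 of the 3, is placed at a copy of that gene on another chromosome, so its reads are uncertain. Of 18 basal and myoepithelial genes, 3 were higher and 1 lower. The hemidesmosome genes ITGB4 (shNC-specific) and LAMA3 (common) were higher (1.45 and 1.02, adjusted p = 0.000254 and 0.000518) and COL17A1, another hemidesmosome gene, was lower in a common region (−1.33, adjusted p = 0.00182). The mesenchymal list had 1 of 14 higher and 3 lower (median −0.24, camera adjusted p = 0.238). ZEB1, a repressor of epithelial genes, was at −0.86 and TNC, encoding tenascin C, at −0.67 (both common, adjusted p = 0.0230 and 0.00846). Neither mesenchymal call was kept without the deeper pair's replicate A, at adjusted p of 0.0989 for ZEB1 and 0.126 for TNC, or without its replicate B, at 0.136 and 0.0778. Counts of higher and lower promoters also moved for the lists. Without the deeper pair's replicate A they were 1 and 1 for squamous, 1 and 0 for luminal, 2 and 1 for basal and 0 and 0 for mesenchymal genes. Without its replicate B they were 1 and 0, 1 and 1, 2 and 1, and 0 and 0. Without the shallower pair's replicate A 7 basal genes were higher, and without its replicate B 1 luminal gene was lower and no mesenchymal gene higher. With equal library totals alone the counts were 1 and 5 for squamous, 1 and 3 for luminal, 2 and 2 for basal and 0 and 7 for mesenchymal genes. None of these lists passed camera, and the adjusted p was 0.912 with an estimated correlation for each.

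Signalling, proliferation and chromatin compaction lists did not pass camera either, at adjusted p of 0.867 each and 0.912 with an estimated correlation. When adjusted over the list alone, 1 more gene was called in each, higher for AP-1, interferon and chromatin compaction and lower for cell cycle and TGF-beta. Among 15 AP-1 family genes 6 were higher and 3 lower in the deeper pair, with ATF3, FOSL1 and FOSL2 higher (1.23, 1.16 and 0.97) and FOS and JUN lower (−0.88 and −0.79), all in common regions. The FOS call was lost without the deeper pair's replicate A (adjusted p = 0.114). Of 29 cell cycle genes 7 were higher and 1 lower, among them CCNE1, encoding cyclin E1 (common, 1.01, SE 0.220, adjusted p = 0.00357, but 0.0658 without the deeper pair's replicate B). Of 24 TGF-beta and SMAD genes 4 were higher and 4 lower, led by SKIL, a repressor of SMAD signalling, among the higher (shNC-specific, 1.48, SE 0.246, adjusted p = 0.000482). Of 16 interferon genes 4 were higher, including ISG20 (common, 1.13), and 2 lower, including IFIT3 (shG8d-specific, −1.77). Of 26 genes on the chromatin compaction and heterochromatin list 9 were higher and 4 lower. The list name does not give the role of each member. PTMA, encoding prothymosin alpha, led the higher (shNC-specific, 1.65, SE 0.251, adjusted p = 0.000242). CBX1, encoding the heterochromatin protein HP1 beta, led the lower (common, −1.22, SE 0.267, adjusted p = 0.00352).

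Counts in these 5 lists were small in several settings. Without the deeper pair's replicate A, 3 AP-1 genes were higher and 0 lower, 1 and 0 cell cycle genes, 3 and 1 TGF-beta genes, 1 and 1 interferon genes, and 1 and 1 chromatin compaction genes. Without its replicate B the counts were 3 and 3, 1 and 1, 1 and 0, 1 and 2, and 1 and 1, in that order. Without the shallower pair's replicate A 4 cell cycle genes were lower. With equal library totals alone the lists had 3 and 3, 2 and 9, 3 and 8, 1 and 3, and 2 and 5.

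The remaining lists showed few calls. Ribosomal protein genes had 2 of 33 higher and 4 lower, snoRNA host genes 1 of 11 in each direction, and HOX, neuronal and stem cell lists none of 5, 5 and 7. Ribosomal counts were 0 and 3 without the deeper pair's replicate A, 1 and 2 without its replicate B, 4 and 4 without the shallower pair's replicate A, and 0 and 7 with equal library totals. Counts for snoRNA hosts were 0 and 0, 0 and 1, 3 and 2, and 0 and 2. The 0 counts of the other lists are of limma calls; without the shallower pair's replicate A, 2 neuronal promoters and 1 stem cell promoter were called higher. Markers of other cell types rarely had a promoter region, 2 of 14 for fibroblasts and 1 of 15 for blood and endothelium. Of these, PDGFRA and CD14 were lower in the deeper pair (−1.50 in a shG8d-specific and −0.89 in a common region), calls that were lost without its replicate A (adjusted p of 0.0644 and 0.0662).

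Most of the largest differences lay outside promoters. Higher in the deeper pair were an intergenic region on chromosome 21 nearest MIR3648-1 (197.3 ± 29.2 against 18.5 ± 9.7 normalized counts, log2 difference 3.43, SE 0.310, limma adjusted p = 7.95e-07), intronic regions nearest MRPS31, DYNC2H1, JAK2 and TEKT4, and intergenic regions nearest CSNK1G3, COX5B, FSHR and MIR4300, with log2 differences from 2.92 to 3.08. The regions nearest MIR3648-1, TEKT4 and COX5B are shNC-specific, where the deeper pair is labelled shNC, and the others are common, where it is labelled shG8d. The region nearest DYNC2H1 had the highest signal, at 1768 ± 146 against 229.2 ± 129. The call nearest COX5B was lost without either deeper library (adjusted p of 0.0535 and 0.0671). Lower in the deeper pair were the promoter of ZNF658B (means 3.26 against 42.1, log2 difference −3.43, SE 0.521, adjusted p = 0.000242) and regions in or nearest MIR3152, RPS29, ERAP2, CWH43, OR4C46, TRAF4, SERTAD4, ASNSP1 and HS6ST2-AS1, from −3.09 to −2.63. Of these, the regions nearest OR4C46 and ASNSP1 are common and the others shG8d-specific. Those of ZNF658B, MIR3152, RPS29, ERAP2, TRAF4, SERTAD4 and HS6ST2-AS1 had means of 3.26 to 7.54 normalized counts in the deeper pair. The size of these differences therefore rests on few reads. The region nearest CWH43 went from 377.9 ± 20.8 in the shallower pair to 52.8 ± 3.9 in the deeper pair. Whether reads in any of the regions of this paragraph belong to copies elsewhere in the genome was not tested.

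Promoters were then listed apart, a choice made after these values were seen. Here they are regions annotated as promoters or lying within 1 kb of a TSS. Some are therefore annotated as introns, 5′ UTRs or transcription termination sites. Over all sets, 8 of the 10 highest came from the shNC-specific set, among them NSD1, encoding a histone H3 methyltransferase (2.27, SE 0.461), and ZBTB9, NCK2 and TMEM250. The NCK2 call was lost without either deeper library (adjusted p of 0.0744 and 0.0704). The 10 lowest all came from the shG8d-specific set, among them the promoter of ADAMTS6 and regions in the first introns of PAICS and TFB1M. How either set was selected is not given, and the same libraries may have been used, so common promoters were listed next. Among the 10 highest common promoters was that of CHD9, a chromodomain helicase gene, with 243.8 ± 30.6 normalized counts in the deeper pair and 61.5 ± 22.4 in the shallower (log2 difference 2.01, SE 0.234, adjusted p = 1.34e-05). KDM4B, encoding a histone H3 lysine demethylase, was at 1.91 (SE 0.235) and GATAD2A, a subunit gene of the NuRD complex, at 1.84 (SE 0.196). The others were SNORA109, MTRNR2L3, CCDC130, STARD9, DHTKD1, SPIDR and SEC61A2. The lowest were GGCX, encoding gamma-glutamyl carboxylase (−2.13, SE 0.258), and BMS1P2, GLUD1P2, USP33, RASGRP3, NFYC, YARS2, IL27RA, HHLA3 and SERF1B. NFYC, a subunit of the CCAAT-binding factor NF-Y, was at 58.0 ± 4.7 against 190.8 ± 15.2 (−1.70, SE 0.209, adjusted p = 2.60e-05). BMS1P2, GLUD1P2 and SERF1B have near-identical copies elsewhere in the genome, so their reads are uncertain. The reads of MTRNR2L3, a nuclear relative of a mitochondrial ribosomal RNA, are uncertain too. For the other promoters, SNORA109 among them, copies were not examined.

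A few regions took an uneven share of reads. The 10 regions of highest signal held 25.8% and 23.7% of the reads of the deeper libraries and 14.3% and 11% of those of the shallower libraries. Regions assigned to MTRNR2L genes, nuclear relatives of a mitochondrial ribosomal RNA, held 6.30% and 5.83% against 3.48% and 2.88%, so most reads of the 10 regions lay outside them. Of 23 such common regions 13 had estimates above 0 (median log2 difference 0.18), as did all 4 in the shNC-specific set (median 2.56). Many lie far from the gene they are assigned to. Within 5 kb of the TSS, a limit chosen after the values were seen, all 11 common regions were above 0 (median 1.73). Farther away 2 of 12 were (median −0.999). Whether reads of other regions of high signal also come from mitochondrial DNA was not tested.

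Libraries of a pair resembled each other more than libraries across pairs. Over 58127 regions (across regions, which are not independent replicates) Pearson's r of log2 values was 0.934 within the deeper and 0.874 within the shallower pair, and 0.689 to 0.793 across. According to the authors' deposited p-values, 14072 regions had an unadjusted p-value under 0.05. Of the common ones, 3614 were higher and 5313 lower under the label shG8d. After Benjamini-Hochberg adjustment 5693 regions of the authors' deposited table passed 0.05, and 5685 of those were also called by limma here, in the same direction.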

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

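Alternatives were fixed before the data were examined, except voom on the recovered reads, adjustment of the deposited p-values, thinning, totals without regions over 1000 normalized counts or mitochondrial copies, and the restriction to common regions. The 13697 calls became 5693 when the deposited p-values were adjusted and 6810 with a 2-fold requirement. They ranged from 4629 to 19153 when each library was left out in turn. There, a lone library is assumed to vary like the other pair. Other settings gave 12965 (thinned) to 18925 (equal library totals). With equal totals 9.87% of calls in common regions and 47.3% in shNC-specific regions were higher in the deeper pair, the latter a reversal of the majority. In the deeper libraries more reads lie in the 10 regions of highest signal. With totals taken without regions over 1000 and without mitochondrial copies, the shares were 40.4% in common and 92.7% in shNC-specific regions. These removals were not run separately. The promoter excess kept its direction and its call in each setting run (odds ratios 2.08 to 3.76). Camera called 1 list, core histones, and 0 with an estimated correlation. Deposited p-values under 0.01 numbered 7480, against 14072 under 0.05.

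With the letter A or B as a replicate block, 15308 regions were called. The letters share only a name, since deviations of same-letter libraries had a correlation of −0.0039 across regions. Of 111 called regions considered for naming, 77 were still called without the deeper pair's replicate A and 81 without its replicate B, 106 and 111 without the shallower pair's B and A, 100 with equal totals and 82 with the deposited p-values. None changed direction in any setting run. Dropping the filter on low values removed no region and says nothing. The count tests fixed beforehand, edgeR and DESeq2, were not run because the deposited unit is log10, and voom on the recovered reads was the read-count test used. GC correction, peak scores, overlap thresholds and motifs were not run, for want of coordinates or scores. At this depth 48% of simulated 2-fold changes were recovered, at a stricter adjusted threshold than that of the data. Differences under 2-fold may be incompletely listed.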

Other observations

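All tests of explanations in this part were chosen after the results were seen. Some neighbourhoods held many calls in 1 direction. Among the genes that were nearest to at least 10 regions, chromosome Y left out, the 5 with the lowest medians were ACTR3BP2, LOC441666, ANKRD30BL, SPIN4 and FAM74A1. ACTR3BP2 on chromosome 2 had 17 of 21 regions called lower in the deeper pair and 0 higher, with a median log2 difference of −1.69. LOC441666 had 17 of 25 lower and 1 higher (−1.45), ANKRD30BL 12 of 15 lower and 1 higher (−1.17), SPIN4 9 of 16 lower (−1.07) and FAM74A1 6 of 10 lower and 1 higher (−0.93). Without the deeper pair's replicate A the lower counts were 15, 16, 10, 8 and 3, and without its replicate B 15, 15, 12, 9 and 1. LOC441666 had 4 higher without the shallower pair's replicate A, and FAM74A1 4 lower without its replicate B. Scaled to equal library totals alone, the lower counts were 18, 18, 14, 9 and 7. These neighbourhoods were picked by their values, and no biological explanation was tested. Whether their reads are placed uniquely, rather than shared with repeated sequence, was not tested either.

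The 5 highest medians had fewer calls. SBNO2 had 4 of 10 regions called higher and 0 lower (0.76), LINC01108 5 of 14 higher and 1 lower (0.74), the phosphodiesterase gene PDE4B 2 of 12 higher and 1 lower (0.68), the keratin gene KRT80 4 of 11 higher (0.68) and MIR3679 3 of 10 higher (0.67). Without the deeper pair's replicate A the higher counts were 1, 1, 0, 2 and 0, and without its replicate B 1, 1, 0, 4 and 0. KRT80 had 7 higher without the shallower pair's replicate A, and without its replicate B the medians of KRT80 and MIR3679 were 0.39 and 0.40. With equal library totals alone SBNO2 had 1 higher (0.41), LINC01108 2 higher and 2 lower (0.40), PDE4B 1 higher and 2 lower (0.34), KRT80 4 higher and 1 lower (0.33) and MIR3679 0 higher (0.32). Each count mixes regions of the common and specific sets, in which the deeper pair has different labels.

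The exchanged labels are the pattern to settle first. Separate normalization of each part of the table argues poorly for it, since factors recomputed within single parts differ from the deposited ones by up to 57.2%. Factors recomputed over all regions, with libraries matched by the value of 1 read, differ from the deposited ones by at most 1.27%, whereas matching by label leaves differences up to 20.7% from those deposited in the common and 24.8% from those in the specific regions. A candidate explanation is therefore that columns were exchanged in one part of the table after a joint normalization. In the specific regions the column labels go with the names of the sets, but set names and columns may share a wrong label, so which part holds the exchange stays open, and with it every direction of the knockdown.

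The authors' shNC-specific regions outnumbered the shG8d-specific ones 7.79 to 1. Of the shNC-specific regions 85.8% were not called once depth was scaled out. The simulation recovered 48% of 2-fold changes, but at a stricter adjusted threshold than that of the data. The recovery of the test in the data is therefore not known, and whether depth in peak calling placed these regions in the set stays open. Of the 2842 called higher in the deeper pair, 2484 (87.4%) were called the same way after thinning the deeper libraries to the shallower depth. Thinning and rescaling keep the expected difference of each region, so this decides nothing about depth, and with equal library totals alone 1220 were higher and 1357 lower. Over the shNC-specific regions the lower quartile of the log2 difference was −0.13, 210 were called lower, and 53.4% showed no overlap between the pairs. Over the shG8d-specific regions the upper quartile was −0.91 and 95.0% showed no overlap. The shNC-specific values argue against selection of that whole set by a difference in normalized counts. Selection from the same libraries by other means stays open, and an effect of the hairpin on these regions stays open and untested.

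The excess of promoters in the deeper pair has several possible explanations. In common regions the promoter minus intergenic difference was 0.24 (bootstrap interval 0.22 to 0.27). Within deciles of mean signal it averaged 0.125 (interval 0.0971 to 0.147), so a trend with signal level may account for part of it. As the whole cause such a trend argues poorly, for these regions and libraries. In deciles 1, 2 and 3, of lowest signal, the difference was 0.065, 0.035 and 0.007, and in decile 9 it was 0.22. The intervals resample regions and leave out the spread between libraries. Between the A libraries the medians were 0.006 at promoters and −0.14 at intergenic regions, and between the B libraries 0.15 and −0.21. Depth stays open, because it is confounded with the pair and the 0.241 after thinning could hardly have moved. A different share of background fragments per library cannot be told apart from an effect of the hairpin. The nearest libraries of the pairs lay 0.130 apart in promoter over intergenic level, less than the 0.17 between the libraries of the shallower pair, and background is confounded with the pair. GC content was not tested.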
